A study of Mus musculus with 2 samples.

How the data were processed

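ATAC-seq libraries of sorted basal cells of mouse back skin, 1 from a CD1 mouse with force-expanded skin and 1 from an untreated CD1 mouse, were analysed from the processed files. Groups were taken from the treatment label of each sample. The submitters' processing notes name Bowtie2 2.2.6, SAMtools, Picard, MACS2 2.1.0.20151222 and HTSeq, and the build GRCm38.

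Peaks were called by the authors with MACS2 on each library alone, per the file headers, from paired-end fragments with a q cutoff of 0.05, without a control file and with summits of subpeaks. Per the file headers, 31944854 and 23876613 fragments remained after filtering. The deposited pileup at each summit is a signal in whole fragments, although the header announces depth-scaled tracks. The deposited -log10 p-values and q-values and the deposited fold enrichment, a ratio, are relative to the local background of the same library. The summit files repeat the deposited -log10 q, and all 95336 and 94190 lines matched the peak tables. The deposited counts are raw counts of each library over the same 109257 merged regions. The program that counted them, whether reads or fragments were counted, whether duplicates were removed first, how shifts for Tn5 were treated and which peak lists were merged are not given in the sources used here. The count of a region reached 74.6 times the summit pileup in the control and 115 times in the stretched library, so the totals, the shares of the 10 large regions and the total scaling may include duplicates. Every listed peak of both libraries lay inside a merged region, and 27044 regions held no listed peak of either. Region starts were read as 0-based and are printed 1-based.

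Libraries were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3) over all regions. The fold is stretched over control, with an exact Clopper-Pearson interval (95%) of the share of the summed count that fell in the stretched library. A region was called higher or lower by a rule of size, a fold of at least 2 with at least 20 counts summed and an interval that excludes 1. With 1 library per group no test was run. Counts without molecular identifiers are not independent molecules, so intervals cover counting error only, and a count of 0 was set to 3 for a point value. Tested on simulated counts for this comparison (94109 regions, Poisson noise with no variation between animals), the rule recovered 100% of 4-fold higher and 78.0% of 4-fold lower regions, and 94.0% and 74.0% at 2.5-fold. Each of these classes held 50 simulated regions. The simulation changed the stretched count alone, which gave higher regions more counts than lower ones, so recovery cannot be compared between the directions. Peak lists were compared with bedtools 2.31.1. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

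Gene positions came from a RefSeq table of the GRCm38 assembly with 21900 protein-coding genes, which has no strand. The plan was to assign a region to the nearest start site within 50 kb. Each region was instead assigned to the nearest annotated end, either end, of a protein-coding gene within 50 kb, and the regions within 1 kb of an end stand in for promoters. A gene at an internal position of a neighbour can therefore receive the neighbour's regions, as Lyl1 does from Nfix. Of the merged regions with at least 20 counts, 70820 were assigned, to 16888 genes. Exons, introns and UTRs were not used here. The planned motif shares need the genome sequence and were not analysed here.

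A gene's fold uses the summed counts of its regions. For the 22 gene lists, fixed before the data were examined, the median log2 fold was ranked among 10000 random lists of the same size matched on the summed count, as a description of these libraries. Named genes followed a rule also fixed before the data were examined. It takes the 10 genes with the largest fold up and the 10 down of a single region with at least 100 counts, the 3 genes of each list with the most changed regions, and 12 genes chosen for the tissue, among them the sorting markers. Bcl11b, Nfkbiz, Twf1, Cwc22, Grm4, Nectin1, Casz1, Flrt2, Osbpl8, Lgr4, Id1, Krt1, Krt10, Ivl and Lor fall outside this rule and were named after their values were seen. The comparison of lower minus higher regions per list was also added after the data were seen. Its first form drew random single regions matched on count, gene density and place, and it put 6 lists at the low end and 3 at the high end, the suprabasal list among them. It was replaced by random lists of whole genes, because regions of the same gene move together, and the second form put 4 lists at the low end and 0 at the high end. Both were computed after the list counts were known.

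Alternatives were scaling by total counts and by DESeq2 1.42.0 size factors, removal of a lowess trend on the count, other count, fold and interval limits, subsets of regions, other overlap rules and other distances to genes. After the data were seen, scaling by the counts outside the 10 regions of over 10000 counts, leaving out those regions, removal of the median of regions of like count and gene density, assignment by gene span and random lists matched on gene density were added.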

Results

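Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in basal cells of the interfollicular epidermis of mouse back skin. The cells were sorted for ITGA6, an integrin subunit of cells attached to the basement membrane, and against CD34, a marker of hair follicle stem cells. There were 2 groups of 1 CD1 mouse each, CD1 being an outbred stock. The skin of 1 mouse had been expanded by mechanical force (the stretched library), the other mouse was untreated (the control library), and 10000 sorted cells went into each library. The control library had 31944854 fragments after filtering and the stretched library 23876613. Counts over 109257 merged regions summed to 8820178 in the control and 11803785 in the stretched library, with medians of 30 and 27 per region. A set of 10 regions with over 10000 counts each held 34.5% of the control counts and 48.9% of the stretched counts, and the regions outside it held 5776423 and 6027023. Whether duplicates were removed before counting is not given in the sources used here, so these totals and shares may hold duplicates. What the 10 regions are was not examined, so other sources of their many counts are not excluded. The region with the most counts, on chromosome 1 from 24611605 to 24616103 (GRCm38), took 19.3% of the control counts and 28.0% of the stretched counts. No group had replicates, so no difference below has a replicate check or a p-value. Every interval is an exact 95% interval for counting error only, except those of the gene-end differences, which come from a bootstrap over regions.

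The peak lists of the 2 libraries were compared first, to see how far the same sites were open in both. Of the 70544 control peaks, 84.5% (84.3 to 84.8) overlapped a stretched peak by at least 1 bp. Of the 75545 stretched peaks, 78.4% (78.1 to 78.7) overlapped a control peak. At regions with a peak in both libraries, the authors' median fold enrichment over local background was 5.43 in the control and 6.73 in the stretched library.

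The comparison of stretched with control cells asked which sites differ in accessibility during expansion of the skin. At Klf6, an immediate-early gene for a zinc finger transcription factor, 8 of 12 regions were at least 2-fold higher in the stretched library, and their summed count was 2.19-fold higher (1.98 to 2.42). At Rxra, which encodes a retinoid X receptor, 18 of 35 regions were at least 2-fold lower and none higher, with a fold of 0.539 (0.515 to 0.564) for the sum. Inside Nfix, which encodes a nuclear factor I transcription factor, on chromosome 8 from 84704712 to 84801238, 15 of 22 regions were at least 2-fold lower and the median fold was 0.394. Copy number at these loci in the 2 outbred animals was not measured. Among genes picked out after their values were seen, Bcl11b, a transcription factor gene, had 16 of 36 regions lower (fold 0.567, 0.535 to 0.601). Nfkbiz, a gene of the IkB family of NF-kB regulators, had 6 of 16 regions higher (1.82, 1.67 to 1.99). Twf1, an actin-binding twinfilin, had all 6 regions higher (2.45, 2.06 to 2.93). With counts scaled by the library totals, 1 region of Klf6, 1 of Nfkbiz and none of Twf1 still passed as higher, while 31 of the Rxra regions and 29 of the Bcl11b regions passed as lower.

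**Figure D1:**
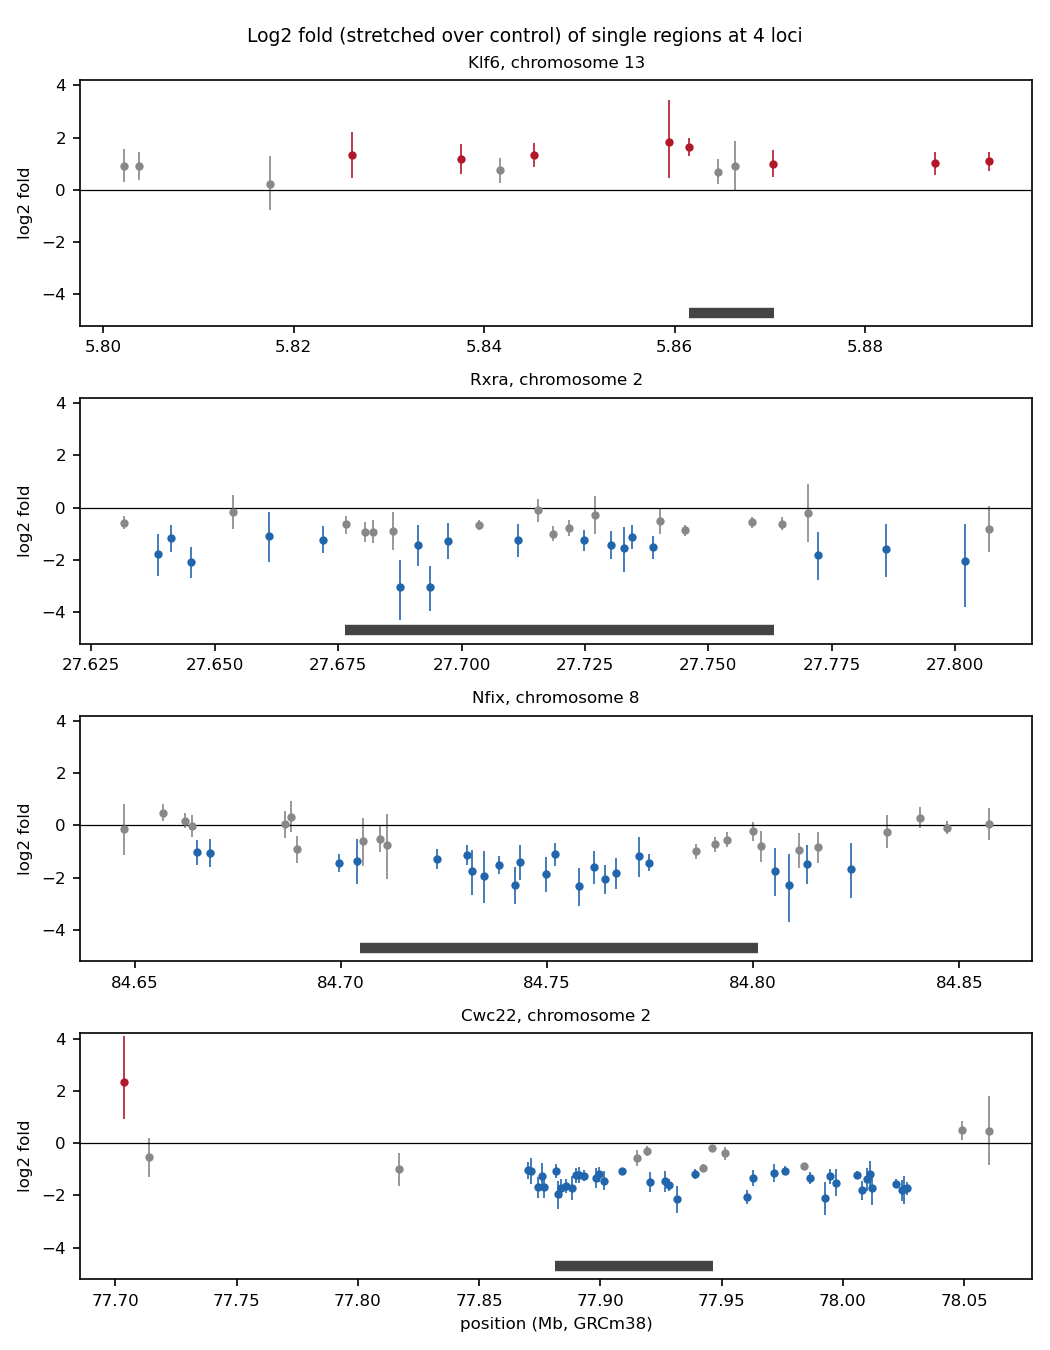
Log2 fold (stretched over control, y axis) against position in Mb on GRCm38 (x axis) for single regions at 4 loci. Points are regions with exact 95% intervals for counting error, red at least 2-fold higher, blue at least 2-fold lower and grey neither, and the dark bar is the annotated gene. At Klf6, 8 regions are higher, and at Rxra, Nfix and Cwc22 runs of neighbouring regions lie below 0.

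Over the 94857 regions with at least 20 counts, 6846 (7.22%) were at least 2-fold higher in the stretched library and 8263 (8.71%) at least 2-fold lower. Simulated counts with counting noise alone, and so without differences between animals or libraries, gave 558 higher and 582 lower calls among 93925 unchanged regions. This split depends on the scaling, since scaling by all counts gave 1590 higher and 22043 lower and scaling by the counts outside the 10 large regions gave 4663 and 11172. These scalings moved the median log2 fold of all regions to -0.50 and -0.14 while the main TMM scaling sets it near 0, so the folds in the text are relative to the median region. Regions with at least 100 counts split the other way, 2165 higher and 1009 lower.

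Taken as whole classes, regions at gene ends and regions far from them differed in direction. Of the 11380 regions touching an annotated gene end, 9.92% (9.38 to 10.5) were higher and 2.46% (2.18 to 2.76) lower. Of the 79178 regions over 1 kb from any gene end, 6.96% (6.79 to 7.14) were higher and 9.58% (9.38 to 9.79) lower. The median log2 fold was 0.30 at gene ends and -0.05 away from them, and it grew with the count in both classes. The difference depended on the count, here with intervals from a bootstrap over regions. At like count and length, gene-end regions lay 0.11 (0.04 to 0.18) below the others from 32 to 64 counts. They lay level with the others from 64 to 128, and 0.20 (0.18 to 0.23) above them from 128 to 256. Direction also varied with gene density, the number of protein-coding genes centred within 500 kb. Among regions not touching a gene end, 10.2% were higher and 7.13% lower at 1 to 2 genes. At over 40 genes these shares were 3.10% and 12.8%. Gene-end regions had 19.4% higher and 0.972% lower at 3 to 5 genes, but 3.54% and 2.61% at over 40.

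**Figure D2:**
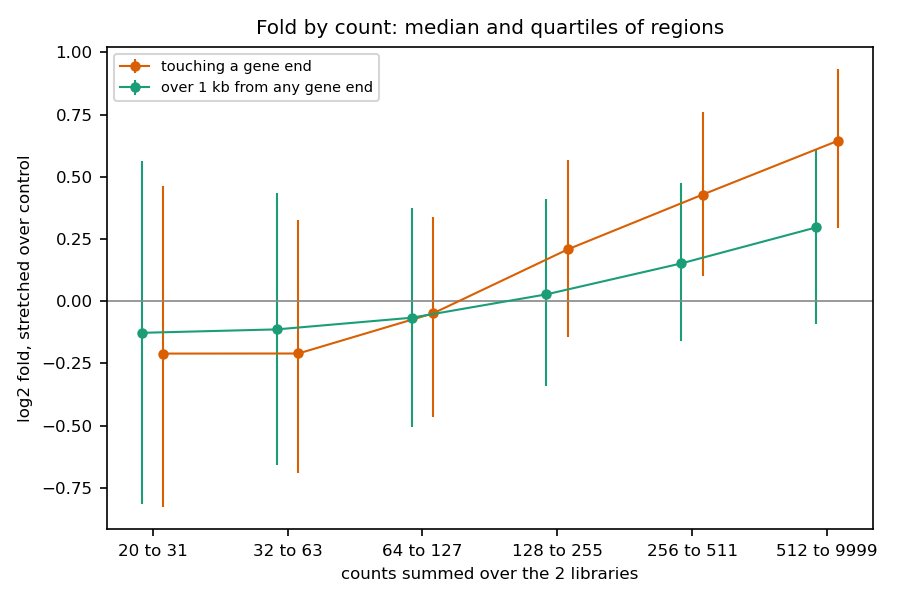
Log2 fold of regions (stretched over control, y axis) by the counts summed over the 2 libraries (x axis, classes), with the median as a point and the quartiles as a bar, for regions touching a gene end (orange) and over 1 kb from any gene end (green). From the lowest to the highest count class the median goes from -0.21 to 0.64 at gene ends and from -0.13 to 0.30 away from them.

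Among single regions with at least 100 counts, those with the largest folds upward were assigned to genes with varied roles. A region 5411 bp from the end of Ap1ar, which encodes a regulator of an adaptor protein complex, on chromosome 3 from 127842934 to 127844133, had 12 control and 93 stretched counts, a fold of 8.19 (4.47 to 16.4). Regions inside Zfp33b, a zinc finger gene (chromosome 5, 104571274 to 104572224), and inside Gosr2, a Golgi SNARE gene (chromosome 11, 103684996 to 103685850), were 7.80-fold (4.35 to 15.2) and 7.61-fold (4.41 to 14.1) higher. The next 7 genes by this rule were Prss12, Cct8, 2610528A11Rik, Samsn1, Slco1a6, C1s1 and Vgll2, with folds from 5.46 to 4.43. Of these, C1s1 encodes a complement protease and Vgll2 a cofactor of TEAD transcription factors. The region assigned to Vgll2 lay 46727 bp from the gene end and that of Cct8 24790 bp, both inside no protein-coding gene.

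The largest folds downward included a region inside 1600014C10Rik on chromosome 7, from 38187788 to 38188116, with 241 control and 2 stretched counts, a control over stretched ratio of 114 (31.2 to 947). Copy number there was not measured in the 2 outbred animals. A region inside Rxra, on chromosome 2 from 27693240 to 27694156, had 121 and 14 counts and was 8.18-fold lower (4.69 to 15.4). A region inside Krt27, a keratin of the hair follicle inner root sheath, on chromosome 11 from 99348539 to 99349221, was 5.18-fold lower (3.16 to 8.95). The others were Nfix, Lyl1 (whose region lies inside Nfix), Gas6, Src, Zfp664, Shisal1 and Stra6, from 4.97-fold to 4.57-fold lower. Stra6 encodes a membrane receptor for retinol uptake, Gas6 a ligand of TAM receptors and Src a tyrosine kinase. The regions of Gas6 and Zfp664 lay 20932 bp and 18021 bp from the gene end, inside no protein-coding gene.

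Genes that define the sorted population changed little, and none reached 2-fold. Krt5, a keratin gene of basal cells, had a fold of 0.979 (0.889 to 1.08). Krt14, its partner, had a log2 fold of 0.26 (0.12 to 0.40), and its fold turned to 0.965 once the trend with count was removed. The sorting markers Itga6 and Cd34 were at 1.17 (1.08 to 1.26) and 1.39 (1.23 to 1.57), and at 0.997 and 0.940 once the median of regions of like count and gene density was removed. At Trp63, the gene of the epithelial transcription factor p63, 4 of 17 regions were higher and 1 lower, with a fold of 1.43 (1.28 to 1.59). The list of basal identity and hemidesmosome genes had 9 higher and 8 lower of 153 regions, against 2 and 22 with total scaling, and lay at percentile 28.0 of random lists, but at 2.72 with gene-end regions alone and 2.66 with regions within 10 kb. In it 6 genes had intervals above 1 and 5 below, and its members Plec and Itgb1 were at 0.876 (0.825 to 0.929) and 1.35 (1.22 to 1.48). With total scaling the fold was below 1 for Krt14, Itga6, Cd34 and Itgb1, and 1.01 for Trp63.

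Regions of 5 fixed gene lists linked to stress, mechanical signals and cell contacts were more often higher than lower. This grouping was not fixed beforehand, and the direction was not particular to it. More higher than lower regions were also found in the YAP and TEAD (13 and 7), cell cycle (11 and 4), chemokine (6 and 3), basal (9 and 8) and housekeeping (3 and 2) lists. The AP-1 list went the other way (4 and 6). For comparison, 6.91% of all 70820 regions within 50 kb of a gene end were higher and 8.52% lower. The stress and wound response list had 12 higher and 2 lower of 90 regions, with 2 higher each at Il33 (an alarmin, fold 1.30, 1.16 to 1.44), Il1b (1.14, 1.02 to 1.27) and Slpi (a protease inhibitor, 1.94, 1.53 to 2.47). The immediate-early list had 12 higher and 4 lower of 97, 8 of the higher ones at Klf6, while Egr2 had 2 higher and 2 lower and Ier5 1 higher. The actomyosin list had 14 higher and 4 lower of 151, with 5 higher regions at Diaph1, a formin that builds actin filaments (1.59, 1.43 to 1.76), but Actn1 had 2 higher and 2 lower (0.989, 0.909 to 1.08) and Myl12b, with 2 higher, a fold of 0.975 (0.877 to 1.08). The desmosome and adherens junction list had 12 higher and 2 lower of 137, 2 of them at each of Dsp (1.26, 1.16 to 1.37), Perp (1.22, 1.12 to 1.33) and Ctnnd1 (1.25, 1.13 to 1.38). The list of EGFR ligands and MAPK feedback genes had 10 higher and 2 lower of 120, with 2 higher at Ereg (1.48, 1.29 to 1.70), 1 higher at Egfr (1.19, 1.10 to 1.29, and 0.969 with count and gene density removed), and 1 higher and 2 lower at Tgfa (0.920, 0.839 to 1.01). All 5 lists turned to more lower than higher regions with total scaling, which lowers every fold. It gave 1006 higher and 16394 lower of the 70820 assigned regions. None of the 5 lists turned when the counts outside the 10 large regions set the scale.

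With the main settings these 5 lists did not stand apart by the measure fixed beforehand, the median log2 fold of a list's genes among 10000 random lists. Their percentiles were 87.9 for the stress list, 49.9 for the immediate-early list, 75.4 for the actomyosin list, 76.9 for the junction list and 65.4 for the EGFR list. Over the settings the junction list ranged from 7.59 (gene-end regions alone) to 87.2 (random lists matched on gene density). The actomyosin list ranged from 22.1 (count trend removed) to 90.05 (the same matching). The stress list did lie outside the central 95% once the count trend was removed (98.0) and once the median of regions of like count and gene density was removed (99.6). In a comparison added after the data were seen, lower minus higher regions were set against random lists of genes of like region number, count and gene density. The stress (0.025), actomyosin (0.435), junction (0.445) and immediate-early (1.58) lists then lay at the low end, and no list at the high end. The place of the immediate-early list came from Klf6, since its other genes had 4 higher and 4 lower regions.

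Single genes of these programmes gave mixed values. At Ccn1 (Cyr61), a target of YAP and TEAD, 3 of 13 regions were higher (fold 1.43, 1.30 to 1.58), whereas Ccn2 (Ctgf), another target, had none changed (0.871, 0.722 to 1.05) and a fold of 0.511 (0.367 to 0.704) at its gene ends. Yap1 had 4 of 16 regions higher (1.46, 1.31 to 1.62), and Ptpn14, a phosphatase gene, 1 higher and 2 lower of 21 (0.900, 0.842 to 0.961). The YAP and TEAD list had 13 higher and 7 lower of 162 regions, which turned to 8 and 10 with the scaling that leaves out the large regions and to 1 and 25 with total scaling, at percentile 41.6. The AP-1 list had 4 higher and 6 lower of 79 at percentile 19.6, with Fos at a log2 fold of 0.37 (0.26 to 0.47), Fosb at a fold of 0.967 (0.879 to 1.06), and Jun, with 1 higher and 2 lower regions, at 1.48 (1.36 to 1.61). Egr1 was at 1.28 (1.15 to 1.41), and at 0.914 with the count trend removed. Krt6a, a keratin of wounded epidermis, had a log2 fold of 0.53 (0.26 to 0.80) with 1 of 3 regions higher, and Krt16, another such keratin, a fold of 0.937 (0.724 to 1.21). With total scaling Fos and Egr1 lay below 1, and Jun, Krt6a, Ccn1 and Yap1 between 1.01 and 1.05.

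Lists of signalling, follicle and differentiation genes were more often lower than higher, with every scaling tried. The scalings by totals lower every fold, so they could not have turned these lists. The list labelled Hippo, Wnt, Notch and BMP signalling had 29 lower and 11 higher of 212 regions. Its median log2 fold of -0.10 lay at percentile 0.55 of the random lists. Its members are Wnt, Notch and BMP genes, while Yap1, Lats2 and other Hippo genes belong to the YAP and TEAD list. At Notch1, a receptor that drives differentiation, 5 of 16 regions were lower (fold 0.663, 0.604 to 0.727). At Lgr6, a receptor for R-spondins, 5 of 14 were lower (0.517, 0.458 to 0.584), and Tcf7l2, an effector of Wnt signalling, had 4 of 16 lower and 1 higher. The list was mixed gene by gene, with 9 genes whose interval lay above 1 and 9 below. Of those above, named after their values were seen, Lgr4, another R-spondin receptor, had 4 of 18 regions higher (1.40, 1.30 to 1.52) and Id1, a BMP target, 2 of 6 (1.85, 1.67 to 2.04), with Lgr4 at 0.993 under total scaling. The list of hair follicle stem cell and outer root sheath markers had 10 lower and 1 higher of 107 regions, at percentile 1.54, with Krt79 at 0.495 (0.399 to 0.610), Lhx2 at 0.713 (0.633 to 0.803) and Lrig1, with 3 of 19 lower, at 0.917 (0.853 to 0.987). The suprabasal differentiation list had 15 lower and 1 higher of 140, but its percentile was 12.0. Its lower share of 10.7% (6.12 to 17.1) and that of the follicle list, 9.35% (4.57 to 16.5), held the 8.52% of all assigned regions. Their higher shares, 0.714% (0.018 to 3.92) and 0.935% (0.024 to 5.10), lay below the 6.91% of all assigned regions. In it Tgm3, an epidermal transglutaminase, had 3 of 17 regions lower (0.733, 0.668 to 0.804), Grhl3 2 of 16 lower (0.733, 0.679 to 0.791), and Grhl1 1 lower and 1 higher (1.44, 1.30 to 1.59).

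**Figure D3:**
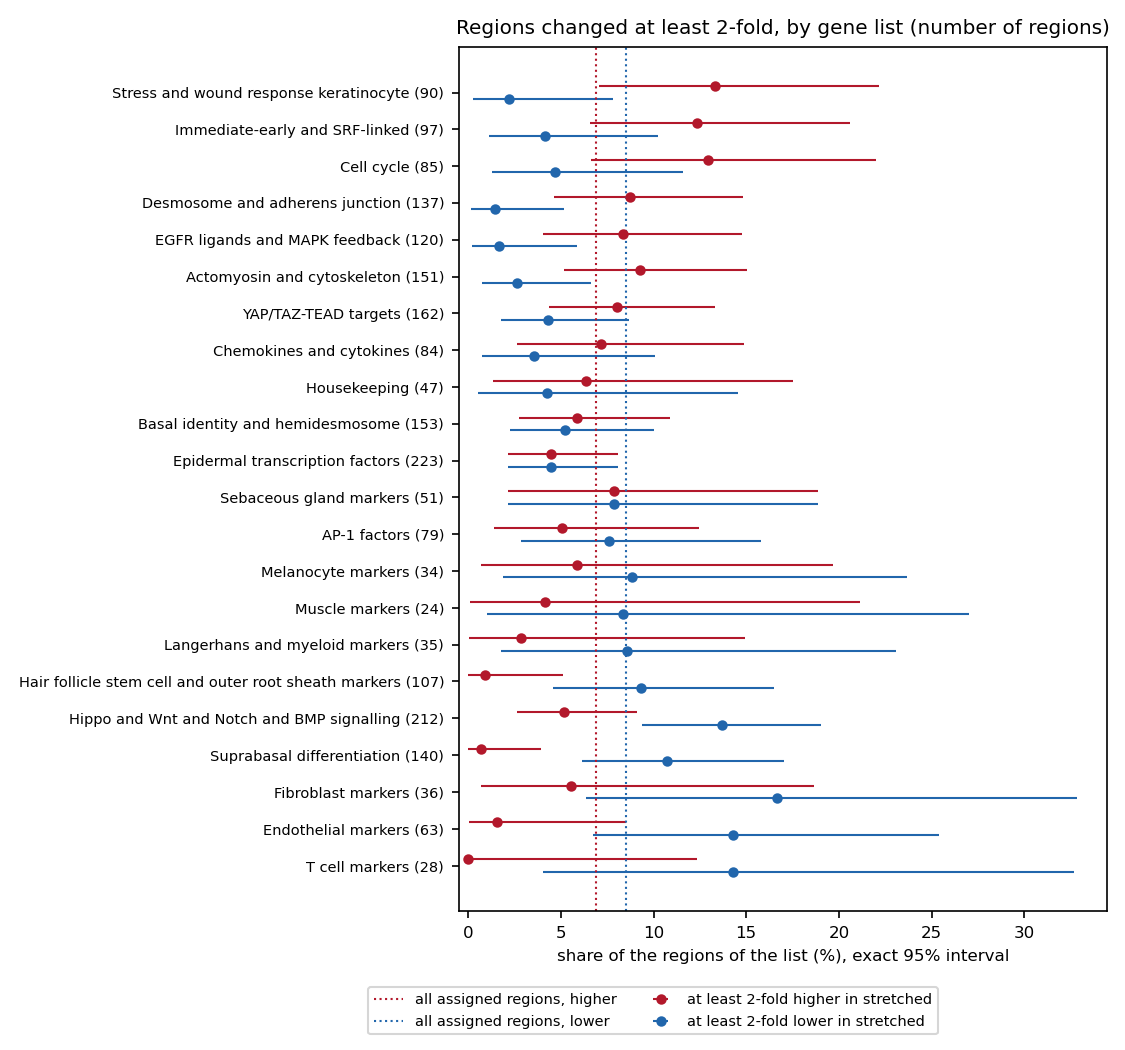
Share of regions at least 2-fold higher (red) or lower (blue) in the stretched library (x axis, %) for the 22 gene lists (y axis, with the number of regions), with exact 95% intervals for counting error and the shares of all assigned regions as dotted lines. The stress and wound list has 13.3% higher and 2.22% lower, the suprabasal list 0.714% higher and 10.7% lower. With total scaling every list has more lower than higher regions, as do all assigned regions (1006 higher and 16394 lower of 70820).

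The cell cycle list had 11 higher and 4 lower of 85 regions, and its median log2 fold of 0.44 lay at percentile 97.8. Of its genes with the most changed regions, Cdkn2a, an inhibitor of cell cycle entry, had 2 higher and 1 lower of 6 regions (fold 1.32, 1.11 to 1.58). Mki67, a marker of cycling cells, had 2 of 8 higher (log2 fold 0.27, 0.13 to 0.41), and Cdk6 2 of 16 (0.13, 0.01 to 0.25), but with the count trend removed the folds of these genes stood at 0.926 and 0.987. The list itself lay further out with the count trend removed (99.5), with count and gene density removed (99.7) and with regions within 10 kb (98.6). With gene-end regions alone it lay at percentile 92.1. With regions counted for the gene span that holds them it lay at 97.46, just inside the central 95%. Scaling that left out the large regions gave 5 higher and 6 lower, and total scaling 2 and 14.

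The T cell, endothelial, fibroblast, Langerhans and myeloid, melanocyte and muscle lists mark cells that the sort was not meant to collect. The sebaceous, epidermal transcription factor, housekeeping and chemokine lists, also given here, are not read that way. Of the 11 listed T cell markers only 6 were measured, 3 of them with a gene-end region. The T cell list had 4 lower and 0 higher of 28 regions (percentile 0.98), the 0 allowing a share of up to 12.3%. In it Cd3e stood at 0.499 (0.350 to 0.702), Thy1 at 0.689 (0.609 to 0.778) and Cd7 at 0.962 (0.814 to 1.14). Endothelial markers had 9 lower and 1 higher of 63 (percentile 1.95), with Tek at 0.633 (0.499 to 0.799), Vwf at 0.753 (0.647 to 0.874) and Erg at 0.760 (0.646 to 0.894). The endothelial list left the extremes in 4 of the alternative settings. It lay at 17.8 with regions within 10 kb and at 5.37 once the count trend was removed. It stayed close to the limit with gene spans (3.54) and with count and gene density removed (2.60). Fibroblast markers had 6 lower and 2 higher of 36 (percentile 17.6), Langerhans and myeloid markers 3 and 1 of 35 (36.9, with H2-Ab1 at 0.654, Cx3cr1 at 0.961 and Ptprc at 1.55), melanocyte markers 3 and 2 of 34 (7.40) and muscle markers 2 and 1 of 24 (20.6). Once the median of regions of like count and gene density was removed, the fibroblast list lay at percentile 0.83 and the melanocyte list at 0.38, both outside the central 95%. Among the melanocyte genes Sox10 stood at 0.597 (0.472 to 0.751), Mlana at 0.876 and Dct at 0.924, and among the muscle genes Acta1 at 0.446 (0.281 to 0.693), Tnnt3 at 0.900 and Acta2 at 1.06, all but Sox10 and Acta1 with intervals that hold 1. Among the fibroblast genes Dpt, Pdgfra and Fbn1 stood at 0.882, 0.875 and 0.995, again with intervals that hold 1. Over all 9 fibroblast genes, 4 intervals lay below 1 and 1 above, and 2 genes were at least 2-fold lower. Sebaceous gland markers had 4 lower and 4 higher of 51 (16.8, with Scd1 at 1.02, Scd3 at 1.11 and Elovl4 at 1.41). Of the 10 sebaceous genes 5 lay above 1, with 3 intervals above 1 and 2 below. Scd1 fell to 0.937 with the count trend removed. Epidermal transcription factors had 10 lower and 10 higher of 223 (61.0) and housekeeping genes 2 and 3 of 47 (85.9). Klf5, a transcription factor gene, had 3 of 9 regions higher (1.63, 1.46 to 1.83) and Ets1 3 of 20 (1.30), and Tfap2a had 1 higher and 2 lower (1.21). Among the housekeeping genes Tfrc had 2 of 4 lower (0.810, 0.674 to 0.971), and Ywhaz and Eef1a1 1 higher each (1.25 and 1.45). Chemokines and cytokines had 3 lower and 6 higher of 84 (6.36, and 2.14 with gene-end regions alone), with 3 higher regions at Ccl20 (log2 fold 0.76, 0.59 to 0.93), 2 higher at Cxcl1 (fold 1.51, 1.29 to 1.76) and 2 lower at Ccl2 (0.751, 0.608 to 0.927). In total 5 of the 22 lists lay outside the central 95% of their random lists, where 1.1 would by chance.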

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

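The alternatives that use gene density, gene spans or the 10 large regions were chosen after seeing the data, and the others before the data were examined. The share of stretched peaks overlapping a control peak was 70.7% with 50% reciprocal overlap, 74.7% for peaks with a -log10 q of at least 10 and 81.5% for equal numbers of best peaks. Higher and lower regions numbered 1590 and 22043 with total scaling, 2165 and 1009 at 100 counts, 13821 and 13042 at 1.5-fold, 761 and 1269 at 4-fold, 3700 and 3408 with a stricter interval, and 2824 and 3043 with a peak in both libraries. The 100 count and shared peak settings keep fewer regions and the stricter interval fewer calls by construction, and the total scaling moves every fold by the same factor. The other settings gave counts within 1.5 times the main ones. Of the 22 lists, 5 lay outside the central 95%, and 3 did with regions counted for the gene span that holds them; the cause was not tested. The same 5 were outside with density-matched random lists. The gene-end setting lost the cell cycle list and gained chemokines, 10 kb lost the endothelial list, and the count trend lost it and gained the stress list. Removing count and density gave 7, without the endothelial list and with the stress, melanocyte and fibroblast lists. Leaving out total scaling, which cannot move a percentile, 102 of 132 percentiles kept their side of 50 and their place inside or outside the central 95%, 30 moved and 0 reversed. Motif shares were not run. No paired analysis was possible because each group has 1 library, and no replicate could be left out. In simulations 5 of 35044 unchanged regions with at least 100 counts passed the rule.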

Other observations

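All tests in this part, and the limits by which each was read, were chosen after the result was seen, and some were revised after a first value was seen, as stated with each. On the X chromosome 327 of 1670 regions were at least 2-fold higher in the stretched library (19.6%, 17.7 to 21.6) and 60 lower (3.59%), with a median log2 fold of 0.44. On the Y chromosome 3 of 32 were higher and 12 lower, and both libraries held counts in its first 2 Mb (205 control, 339 stretched). On chromosome 11 198 of 6529 were higher (3.03%) and 859 lower (13.2%), with a median of -0.21. None of these chromosome shares was matched on gene density. Further genes with many changed regions, chosen after their values were seen, were Grm4, a glutamate receptor gene, with 11 of 14 regions lower, Nectin1, an adhesion molecule gene, with 9 of 27 lower, Casz1 with 8 of 35 lower, and Flrt2 and Osbpl8 with 7 of 12 and 7 of 13 higher. With total scaling 11 of the Grm4, 20 of the Nectin1 and 19 of the Casz1 regions passed as lower, and 1 each of Flrt2 and Osbpl8 as higher. Beside 1600014C10Rik on chromosome 7, from 38175940 to 38190103, 5 regions had 663 control and 19 stretched counts in sum, while the region among them from 38182668 to 38184292 had 550 and 366 (log2 fold -0.51). The 32 neighbouring regions had a median log2 fold of 0.32. Copy number was not tested there, and a difference between the 2 outbred animals is not excluded.

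Regions touching a gene end were higher in the stretched library than other regions, by 0.35 in the median log2 fold, and a difference in enrichment over background would raise regions of high count. Averaged over regions of like count and length a difference of 0.19 (0.17 to 0.21, bootstrap over regions) stayed (0.20 with the coarser classes tried first), which argues against a trend shared by all regions of like count as the whole cause. The average hides a turn, from -0.11 (-0.18 to -0.04) at 32 to 64 counts to 0.31 (0.26 to 0.38) from 512 counts, so a trend with count that is steeper at gene ends is not excluded. Gene density, a stand-in for GC content, was not the whole cause either, since at like density the difference was 0.44 (0.42 to 0.45). GC content itself, transposition and size selection of the libraries, and an effect of stretching stay open, because each library is 1 animal and no sequence was used.

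A block beside Cwc22, on chromosome 2 from 77869720 to 78027118, held 45 regions, all 45 below 1 and 39 at least 2-fold lower, with a median log2 fold of -1.32; its bounds were set after the values were seen. Cwc22, a splicing factor gene, lies in a segment known to vary in copy number among mouse stocks. Counts per kb in the block were 5.98 times those of all regions (8.33 in the control, 3.22 in the stretched library), so a different copy number in these outbred animals is a candidate explanation. A change of chromatin in the stretched animal cannot be told apart from it, because the SD of the log2 fold over the block, 0.44, is above the 0.18 that counting error gives and below the 0.65 of windows of adjacent regions. Copy number was not tested at Nfix and is not excluded there: all 22 regions from 84703564 to 84794299 on chromosome 8 lay below 1, with counts per kb 2.75 times those of all regions in the control and 1.01 times in the stretched library.

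Regions of the suprabasal differentiation list were more often lower than higher, 15 against 1. With the median of regions of like count and gene density removed they numbered 8 lower and 0 higher of 140. All 70820 assigned regions then had 4641 lower and 4998 higher. Count and gene density, as a stand-in for GC content, may account for part of the excess of lower regions. Lower minus higher regions lay at percentile 93.9 among random lists of matched genes. An earlier form with single matched regions gave 99.3, which treats regions of the same gene as independent, so the call rests on that choice. Fewer suprabasal cells in the stretched sort cannot be told apart from a change in basal cells, since 11 of 18 genes (61.1%) lay below 1 with the median of regions of like count and density removed, a test that replaced a first look at 10 late genes (4 intervals below 1, 2 above). Of genes named after their values were seen, Krt1 and Krt10 were at 0.629 and 0.598 but Ivl and Lor at 1.22 and 1.24. Lor fell to 0.996 with the count trend removed. The sort for ITGA6 should leave out most suprabasal cells.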
